A study of Picea glauca with 4 samples.

How the data were processed

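Shoot tips of white spruce (Picea glauca) from a full-sib mapping family were compared on 29 two-colour spotted oligonucleotide arrays. Per the labels, the arrays make up 4 comparisons. Early against late time-to-bud-set trees were hybridised at Time 1 (6 arrays) and at Time 2 (5 arrays). Time 1 was hybridised against Time 2 in early trees (8 arrays) and in late trees (10 arrays). Per the labels, channel 1 (Alexa647, read at 635 nm) held the early trees or Time 1, and channel 2 (Alexa555, read at 532 nm) held the late trees or Time 2. The same orientation was used on every array, so no dye swap cancels a dye effect of a probe. The labels call the arrays of a comparison biological replicates, while the design text names 2 biological replicates per time and class; which tree is on which array is not given in the sources used here. The p-values therefore measure the spread between arrays, some of which may share trees or genotypes, and may be too small for statements about trees. Trees could not be kept as a block.

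The spot intensity values are scanner pixel brightness on a linear scale; per the file headers these intensities were quantified by the authors with GenePix Pro (versions 6.0.1.27 and 6.1.0.4), with no normalization applied. The percent of saturated pixels of each spot comes from the same program, per the file headers. The spot flag is a score set by that program, per the file headers, where -100 stands for a bad spot. The authors also deposited a value table with 1 log2 ratio per spot and comparison; its values follow the mean over the arrays of 635 nm over 532 nm log2 ratios, while the background correction and normalization behind it are not given in the sources used here. Scale and direction of that table were settled against the scanner values. Its column medians over 34992 spots were 0.0326 and 0.015 for the early against late comparisons at Time 1 and Time 2, and 0.0628 and 0.058 for the time comparisons in early and late trees. How it was centred stays unknown.

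Each array held 34992 spots in 48 blocks. Of these, 32144 were spruce probes, each printed once, and 1274 were control spots named GFP or Alien. The remaining spots were named Empty, Buffer or BLANK. None of the files used here pairs the probes with gene names, so probes are given by ID. The 24 gene lists fixed before the data were examined were therefore not analysed here, and neither were markers of other tissues.

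Mean foreground and median local background were background-corrected with normexp (offset 50) and normalized within each array by loess, with weight 0 for control spots and bad spots. Bad spots were then set missing. Log2 ratios were oriented as early over late for the class comparisons and as Time 2 over Time 1, as labelled, for the time comparisons. Each comparison was fitted by limma (version 3.58.1, R 4.3.3, statmod 1.5.0) with 1 mean per comparison and moderated variances, and p-values were adjusted by Benjamini-Hochberg over the 32144 probes. A probe was called at an adjusted p under 0.05. The difference of the time change between early and late trees was tested over the 18 arrays of the time comparisons, and the difference of the early-late difference between times over the 11 arrays of the class comparisons.

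A channel of a spot was counted as well above background when its median foreground exceeded the local background by 2 background SDs. A spot was counted as saturated with over 50 percent of pixels saturated in either channel. Where a probe was not well above background on any array of a group, a floored fold from loess and Aquantile normalized channel values is given. For it, that group's values were raised, where lower, to the lowest value of any spruce probe well above background in that channel and array. A floored fold is an estimate that leaves out the spread between arrays, so the true fold may be smaller. It is also open to dye bias without dye swaps. Probes above the control-spot limit are those whose background-subtracted median exceeded the 95th percentile of the GFP and Alien spots in at least 1 channel on at least 50 percent of the arrays. No array was a repeat deposit of another: the highest correlation of log2 ratios between any 2 arrays was 0.83.

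Probes named in the text follow a rule fixed before the data were examined for the case of unnamed probes. It takes the 2 probes with the largest rise and the 2 with the largest fall in log2 ratio, here among those called in a comparison. Where none was called, the 2 rises and 2 falls of smallest p are named, a choice that the fixed rule did not contain. The number of arrays limits the precision. On arrays simulated from the real spread, the fit recovered 83.3% of 4-fold and 38.8% of 2-fold changes for early against late at Time 1, and 43.9% and 1.49% at Time 2. The corresponding shares were 98.5% and 56.7% for the time change in early trees, and 98.5% and 73.1% in late trees. For the difference of the time change they were 90.9% and 56.7%, and for the difference of the early-late difference 63.6% and 2.99%. Each simulation changed 66 probes by 4-fold and 67 by 2-fold among 32144. All were drawn from probes well above background in either channel on at least 50 percent of the arrays. With so few changed probes the Benjamini-Hochberg threshold is stricter than where many change, so these shares are not the power of the real comparisons.

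Batches were taken from the scan times in the file headers. The time arrays were scanned in an earlier period (2 arrays of early and 4 of late trees) and a later period (6 of each). The class arrays were scanned last, with all 6 arrays of Time 1 and 1 array of Time 2 on the same day and the other 4 arrays of Time 2 on another day. The alternatives were other background corrections, other normalizations, filters on dim probes, median in place of mean foreground, other flag rules, other variance models, other thresholds, scan batch as a block, within-period fits and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.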

Results

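Bud set is the end of shoot growth in autumn, when the shoot tip forms a closed winter bud. The series design text describes 2 classes of trees in a white spruce full-sib family, those that fell in the outer quartile for early or for late bud set in at least 3 of 6 trait experiments. Time 1 is the harvest of shoot tips when buds began to form, and Time 2 the harvest 6 weeks later, with most buds about midway. Plants were kept at 16 h light, 8 h dark and 20 °C per the labels. The arrays asked which transcripts change while the bud forms, in each class, and which differ between the classes at each time. Per the design text, 4 ramets (clonal trees) were harvested per genotype, 2 of them at each time. Trees of the 2 times may thus share a genotype but are different ramets. The design text names 2 biological replicates per time and class, fewer than the arrays of any comparison, and no label ties an array to a tree. Arrays of a comparison may therefore share trees or genotypes, so n counts arrays, and p-values over arrays may be too small for statements about trees. The 29 arrays gave median background-subtracted signals over the 32144 spruce probes of 136 to 1041 in the Alexa647 channel and of 198 to 974 in the Alexa555 channel. Between 40.1% and 80.7% of spruce probes were well above background in the Alexa647 channel, and between 26.0% and 75.5% in the Alexa555 channel.

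The time labels of the 2 kinds of array ran against each other. The 210 probes that were at least 8-fold higher at labelled Time 2 in both tree classes had array medians of 2109 to 8470 in both channels of the 6 class arrays labelled Time 1. On the 5 class arrays labelled Time 2 the same probes gave 126 to 544. The 18 probes that were at least 8-fold lower at labelled Time 2 showed the reverse, with medians of 66 to 960 on the arrays labelled Time 1 and of 4486 to 19270 on those labelled Time 2. Of the 3600 probes that changed at least 2-fold in the same direction in both tree classes, 3589 (99.7%) had a brightness difference of the opposite sign on the class arrays. Across the 25185 probes above the control-spot limit in any comparison, the brightness difference of the class arrays (labelled Time 2 minus labelled Time 1) correlated with the labelled time change at r = -0.896, with a slope of -0.958; probes are not independent replicates. Each class array's slope on the time change lay on the side of the other label, with means of 0.479 ± 0.133 (SD, n = 6) for labelled Time 1 and -0.479 ± 0.045 (SD, n = 5) for labelled Time 2 (exact permutation test over 462 splits, two-sided, p = 0.00216, the smallest it can give). Slopes were taken on brightness less the midpoint of the 2 labelled group means, so these 2 means are equal and opposite by construction. Single arrays ranged from 0.364 to 0.719 under labelled Time 1 and from -0.541 to -0.428 under labelled Time 2. The labels and file headers do not settle which of the 2 is exchanged. Time 1 and Time 2 are therefore given as labelled throughout. With the channels of the time arrays exchanged, higher and lower change places in every value of the time change; with the class arrays exchanged, the 2 early-late comparisons change names. Counts of called probes are the same either way.

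**Figure D1:**
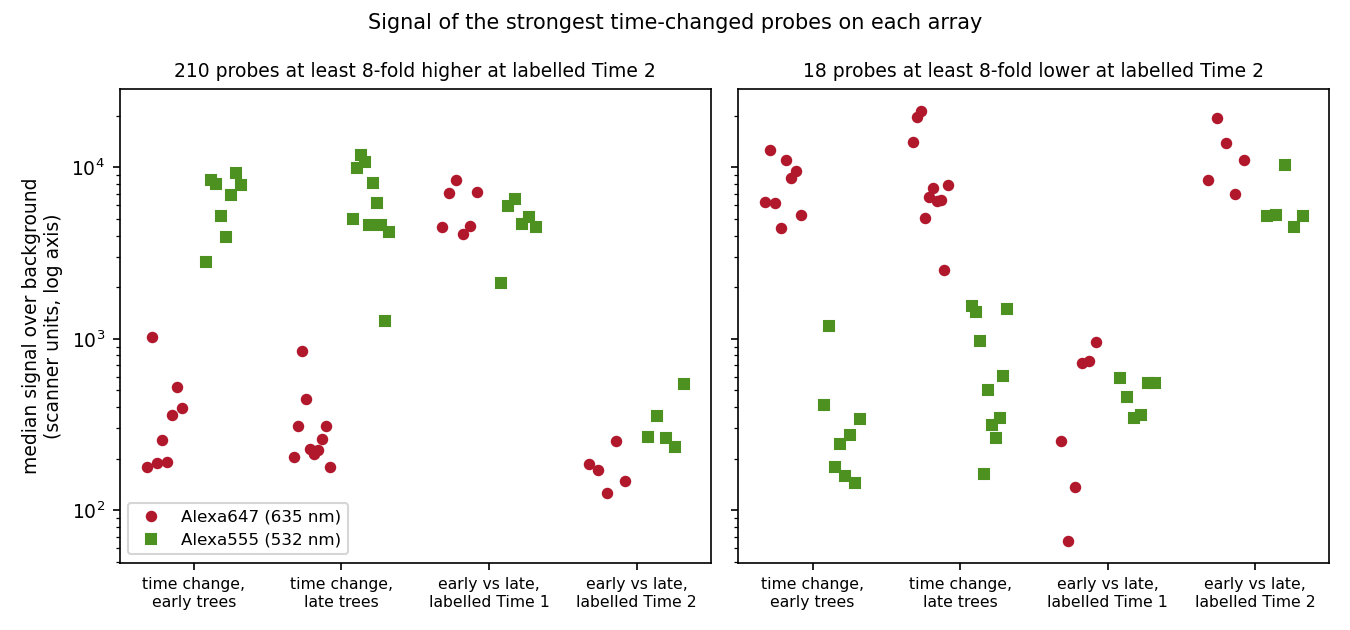
Median background-subtracted signal per array (scanner units, log axis) of the 210 probes at least 8-fold higher (left) and the 18 probes at least 8-fold lower (right) at labelled Time 2 in both tree classes; each point is 1 array and channel. On the time arrays the probes of the left panel are bright in the Alexa555 channel (labelled Time 2), yet on the class arrays they are bright in both channels under the label Time 1 (2109 to 8470) and dim under Time 2 (126 to 544).

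In early trees, the change from Time 1 to Time 2 involved a large part of the probes. Among called probes, the largest rises were those of Spruce_16623, which was 50.9-fold higher at labelled Time 2 (log2 ratio 5.67 ± 1.30, SD, n = 8), and Spruce_31785, 45.5-fold higher (5.51 ± 1.25, n = 8). The largest falls were those of Spruce_22387 (log2 ratio -4.59 ± 1.26, n = 8) and Spruce_14926 (-4.52 ± 1.36, n = 8). Each of these 4 probes kept its direction on 8 of 8 arrays, with limma adjusted p between 7.18e-06 and 3.26e-05; Spruce_16623 was saturated on 2 arrays, and at labelled Time 2 Spruce_22387 and Spruce_14926 were well above background on 2 and 5 of 8 arrays. In total 12877 of 32144 probes were called (40.1%), 6846 higher and 6031 lower at labelled Time 2. Large changes were more often rises: 968 called probes were at least 4-fold higher and 323 at least 4-fold lower. The scan periods gave 12039 calls on the 6 later arrays and 2064 on the 2 earlier ones, and the fit with scan period as a block gave 11429.

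In late trees the time change had a similar extent. Spruce_20463 was 51.4-fold higher at labelled Time 2 (log2 ratio 5.68 ± 1.60, SD, n = 10) and rose on 10 of 10 arrays, though at labelled Time 1 it was well above background on only 2 of 10. Spruce_02285 was 49.6-fold higher (5.63 ± 2.18, n = 10), on 9 of 10 arrays. Spruce_05340 (-4.82 ± 0.931, n = 10) and Spruce_22387 (-4.71 ± 0.946, n = 10) fell most among called probes, each on 10 of 10 arrays; at labelled Time 2 they were well above background on 3 and 6 of these. The limma adjusted p of these 4 probes lay between 6.72e-07 and 2.5e-05. In total 13030 probes were called (40.5%), 6940 higher and 6090 lower at labelled Time 2, of which 840 were at least 4-fold higher and 199 at least 4-fold lower. Within scan periods 9203 probes were called on the 6 later arrays and 5913 on the 4 earlier ones, and 12553 with scan period as a block.

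The probes that changed with time were largely shared by early and late trees. Probes higher at labelled Time 2 in both classes numbered 5749, where 1478 would be shared by independent lists of these lengths, and 4531 were lower in both, against 1143. Only 1 probe was called in opposite directions. Among the shared probes, 2439 were at least 2-fold higher and 1161 at least 2-fold lower in both classes, and 36 and 4 were at least 16-fold higher and lower. Across the 32144 probes the 2 time changes correlated at r = 0.954, and as high a correlation came from 3 of 65536 sign patterns of the arrays, whose highest other reached 0.956 and whose median was 0.389 (exact permutation test, two-sided, p = 4.58e-05). The correlation was 0.948 among arrays of the later scan period and 0.799 among those of the earlier one. Probe by probe, Spruce_16623 was also 5.26 ± 1.96 (log2 ratio, SD, n = 10) higher in late trees, Spruce_31785 5.44 ± 1.48 and Spruce_14926 -3.40 ± 1.18. In late trees Spruce_16623 was saturated on 2 of 10 arrays and well above background at labelled Time 1 on 3 of 10, and Spruce_31785 was saturated on 1 of 10. Spruce_14926 was well above background at labelled Time 2 on 5 of 10. In early trees Spruce_05340 fell by 4.43 ± 0.96 (SD, n = 8), and was well above background at labelled Time 2 on 1 of 8 arrays. Spruce_02285 differed most between the classes among these probes: in early trees it rose by 3.33 ± 2.59 (log2 ratio, SD, n = 8, adjusted p = 0.00814), on 7 of 8 arrays, and fell on array 2 (log2 ratio -1.41). Spruce_20463 was not well above background in the Alexa647 channel (labelled Time 1) on any of the 8 arrays of early trees. By floored fold it was there 23.9-fold higher at labelled Time 2 (adjusted p = 7.09e-06). Of the 2596 probes called in early trees alone, 2509 (96.6%) had the same sign in late trees, and of the 2749 called in late trees alone, 2673 (97.2%) had the same sign in early trees.

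**Figure D2:**
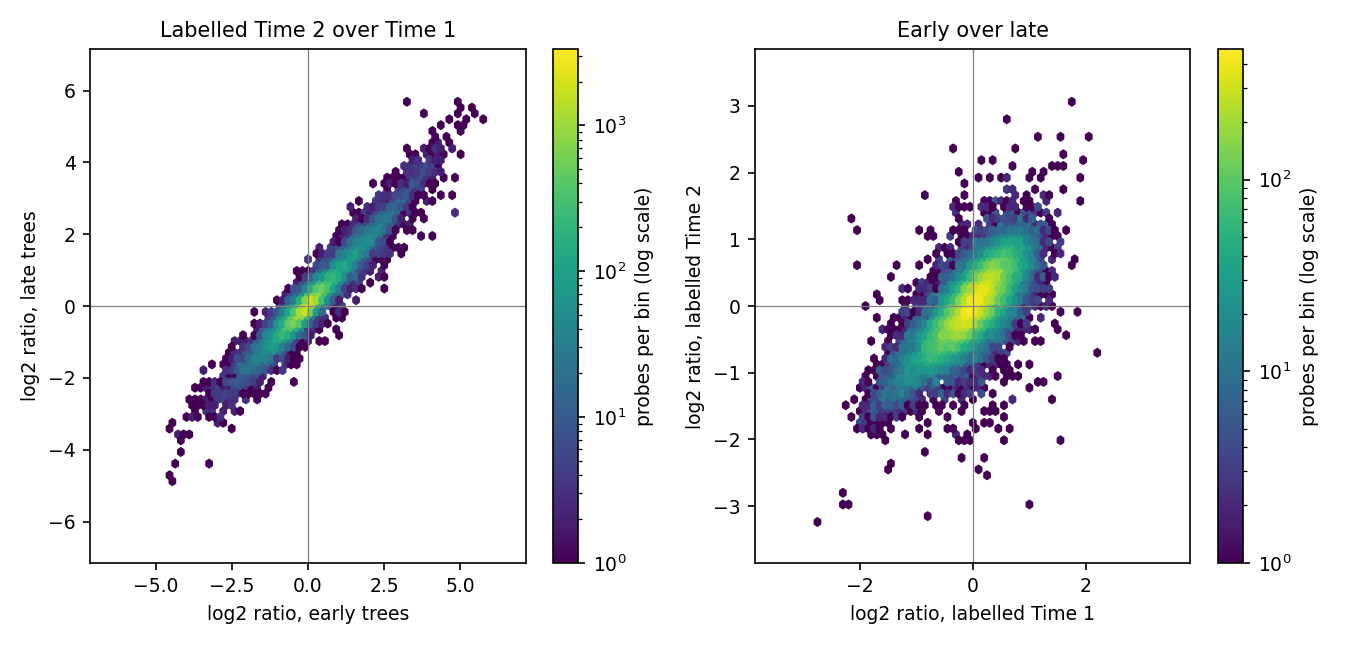
Log2 ratios of the 32144 spruce probes, as counts of probes per hexagon (log colour scale). Left, labelled Time 2 over Time 1 in late trees (y axis) against early trees (x axis), r = 0.954; right, early over late at labelled Time 2 (y axis) against labelled Time 1 (x axis), r = 0.742.

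No probe was called for a difference of the time change between early and late trees (limma, 18 arrays), and 895 had an unadjusted p under 0.05 where chance alone gives 1607. A count under that of chance means that these p-values may not be well calibrated, and is no evidence of equal time changes. A test on each probe without shared variances also called 0. Early and late trees were both read with Time 1 in the Alexa647 channel, so a dye effect of a probe cancels in this difference but not in either time change. The 95% confidence interval of the difference lay within 2-fold for 27763 probes (86.4%), and for 82.7% of those above the control-spot limit. The probes of smallest p were short of the threshold, all with an adjusted p of 1. Spruce_24410 had log2 ratios of -3.37 ± 0.827 (SD, n = 8) in early and -1.85 ± 0.842 (n = 10) in late trees, and was well above background at labelled Time 2 on 4 of 8 and 7 of 10 arrays. Spruce_19514 had 1.19 ± 0.807 and -0.017 ± 0.444, Spruce_27937 had -0.40 ± 0.394 and 0.44 ± 0.436, and Spruce_19309 had 0.40 ± 0.53 and -0.34 ± 0.229. Over the 18 arrays Spruce_19309 was under the control-spot limit, and at labelled Time 2 it was well above background on 2 of 8 arrays of early and 4 of 10 of late trees. Without array 4 of the early trees, 1 probe was called, Spruce_19514, with an adjusted p of 0.0305 (0.0305 to 1 over its 20 alternatives).

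At labelled Time 1, early and late trees differed at 4594 of 32144 probes (14.3%), 1722 higher and 2872 lower in early trees. The count depended on the processing: it was 12445 with median centring in place of loess, 3420 of them among the 4594, and 2633 with a test on each probe without shared variances. By fitted log2 ratio, the largest rise among the 4594 probes was that of Spruce_16290, 4.09-fold higher in early trees (log2 ratio 2.03 ± 1.52, SD, n = 6, adjusted p = 0.0234), on 6 of 6 arrays. Its call was lost without array 1, 3 or 4 (adjusted p of 0.0644, 0.0529 and 0.0505, with 0.00864 the lowest over its 8 alternatives), and late trees were well above background on 2 of 6 arrays. Spruce_23076 was not well above background in late trees on any array. By floored fold it was 2.99-fold higher in early trees (n = 6, adjusted p = 0.0142), on 5 of 6 arrays, with early trees well above background on 4 of 6. Which of these 2 rises was larger could not be told. Spruce_01027 was 4.81-fold lower in early trees (-2.27 ± 0.272, n = 6), which were well above background on 2 of 6 arrays. Spruce_00074, not well above background in early trees on any array, was 3.79-fold lower by floored fold (n = 6). Each fell on 6 of 6 arrays with an adjusted p of 0.00119, and which fall was larger could not be told. Differences were smaller than with time: by fitted ratio 1240 called probes differed at least 2-fold, 273 higher and 967 lower, and 7 differed at least 4-fold.

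The probes that differed between the classes were mostly dim ones. Of the 4594, 3462 (75.4%) lay in the dimmer 5 of 10 equal groups of probes by brightness, against 34.3% and 34.5% of the time calls in early and late trees. The share called fell from 16.9% in the dimmest group and 27.2% in the next to 3.23% in the brightest. Calls in the dim groups were mostly lower in early trees. Only 10 of 542 were higher in the dimmest group and 113 of 874 in the next, against 58 of 104 in the brightest. The median early over late log2 ratio of the probes was -0.17 in the dimmest group, -0.193 in the next and 0.0733 in the brightest. The excess of lower over higher calls among the 4594 thus lay in the dimmest groups. The control spots named GFP and Alien carried a median Alexa555 signal of 137 to 273 on these 6 arrays and of 2 to 34 in the Alexa647 channel. On the time arrays they carried 5 to 34 in the Alexa555 channel. Among the 18890 probes that passed the filter against local background, 1192 were called, 464 higher and 728 lower. Among the 22564 above the control-spot limit, a filter chosen after seeing the data, 2061 were called, 1052 higher (51.0% against 37.5% of all calls) and 1009 lower. A probe passes that limit with 1 channel. Its value on these 6 arrays was 47 to 95.7 for Alexa647 (early trees) and 420.7 to 724.7 for Alexa555 (late trees). Median spruce signals were 187 to 336 and 342 to 481.5, above the former limit and below the latter. Passing thus favours probes high in early trees, so the larger share of higher calls can come from the filter itself. Leaving out array 2, 5 or 6 brought the count to 2146, 2210 or 2117. All 6 arrays were scanned on 1 day, so no scan batch could be set apart, and early trees were in the Alexa647 channel throughout, so a dye effect of a probe is part of its ratio.

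**Figure D3:**
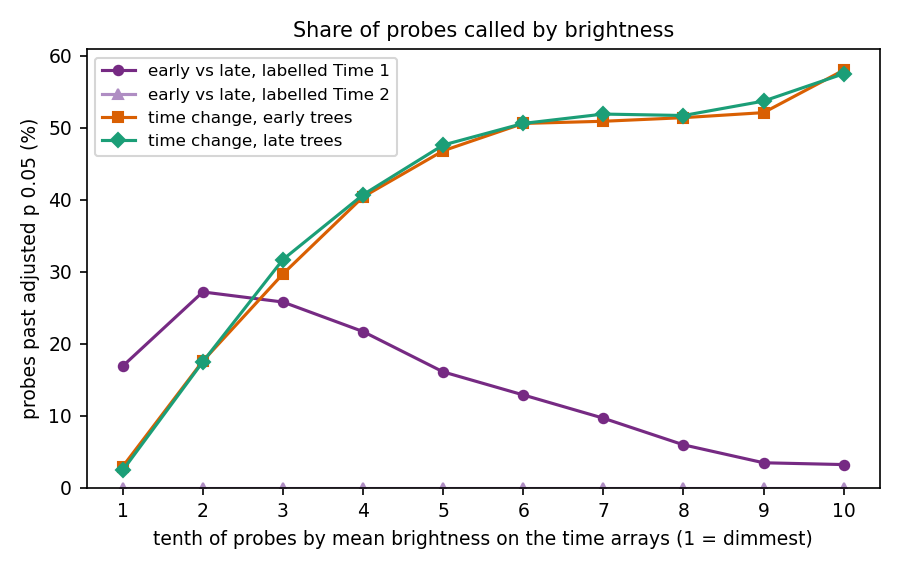
Percent of probes past an adjusted p of 0.05 (y axis) in each of 10 equal groups of the 32144 spruce probes, ordered by mean brightness on the time arrays (x axis, 1 is dimmest), for the 4 comparisons. The early-late calls at labelled Time 1 fall from 27.2% in group 2 to 3.23% in the brightest, while the time calls rise to 58.0% and 57.5%.

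**Figure D4:**
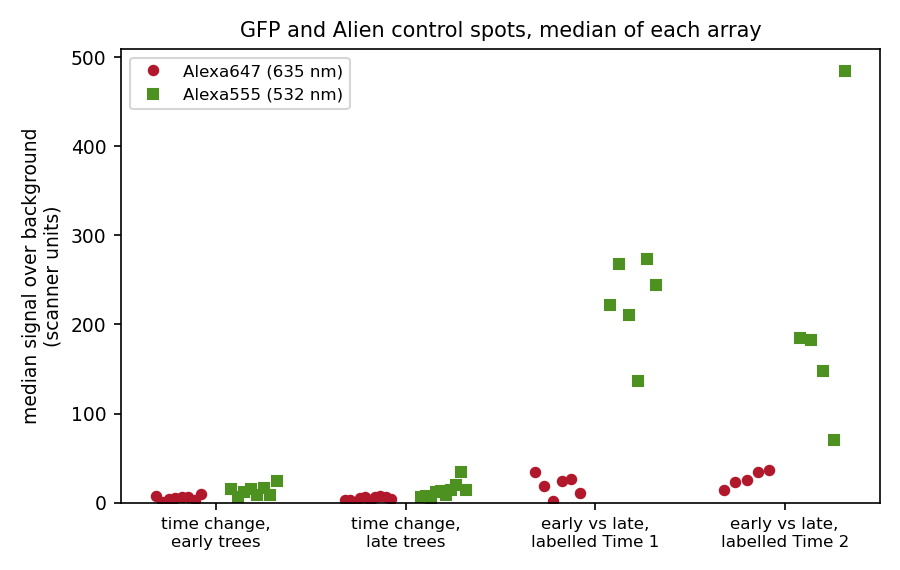
Median background-subtracted signal (scanner units) of the 1274 control spots named GFP and Alien on each array, by channel. In the Alexa555 channel the class arrays lie between 70 and 484.5 and the time arrays between 5 and 34, while no array exceeds 37 in the Alexa647 channel.

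At labelled Time 2, no probe passed the threshold between early and late trees (limma, 5 arrays, smallest adjusted p 0.121), and 6270 had an unadjusted p under 0.05 where chance alone gives 1607. A test on each probe without shared variances called 0 as well, while a fit of all 29 arrays together, with a shared variance, called 5686, and median centring in place of loess called 1532. The probes of smallest p, short of the threshold with loess and past it with median centring (adjusted p of 0.0389, up to 0.408 over their 7 alternatives), had an adjusted p of 0.121 and the same direction on 5 of 5 arrays. Spruce_20695, not well above background in late trees on any array, was by floored fold 3.40-fold higher in early trees (n = 5), which were well above background on 3 of 5. Spruce_07292 had a log2 ratio of 2.55 ± 0.707 (SD, n = 5) and Spruce_01781 of -2.42 ± 0.882, with late trees well above background on 2 of 5 arrays for the former and early trees on 1 of 5 for the latter. Spruce_05550, not well above background in early trees on any array and under the control-spot limit, was 1.58-fold lower by floored fold, although late trees were well above background on only 2 of 5 arrays. With 5 arrays, the 95% interval lay within 2-fold for 20208 probes (62.9%), and for 59.6% of those above the control-spot limit. With scan day as a block, which gives the array scanned on the first day as much weight as the other 4 together, 3389 probes were called; on those 4 arrays alone 0 were called.

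The early-late differences at both times ran in the same direction. Of the 4594 probes called at labelled Time 1, 4484 (97.6%) had the same sign at labelled Time 2, and across all probes the 2 differences correlated at r = 0.742. No other of the 512 sign patterns of the arrays gave as high a correlation, though the highest other reached 0.726 and their median was 0.249 (exact permutation test, two-sided, p = 0.00195, the smallest it can give). Among the 21200 probes above the control-spot limit at both times r was 0.733, and in the brightest of the 10 groups it was 0.677. Spruce_16290, the largest called rise at labelled Time 1 by fitted ratio, had a log2 ratio of 2.58 ± 2.15 (SD, n = 5, adjusted p = 0.133) at labelled Time 2. Spruce_01027, the largest called fall by fitted ratio, had -1.52 ± 0.887 (n = 5, adjusted p = 0.121), with early trees well above background on 1 of 5 arrays. At labelled Time 1, Spruce_07292 was not well above background in late trees on any of 6 arrays. By floored fold, here equal to its fitted fold, it was 2.19-fold higher in early trees (adjusted p = 0.0317), which were well above background on 3 of 6. Spruce_01781 was not well above background in early trees on any of 6 arrays. By floored fold it was 2.49-fold lower there (adjusted p = 0.00632), with late trees well above background on only 2 of 6.

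No probe was called for a difference of the early-late difference between times (limma, 11 arrays), and 985 had an unadjusted p under 0.05 where chance alone gives 1607. Here too the count under that of chance is no evidence of equal differences. A test on each probe without shared variances called 0, and the fit with scan day as a block called 7. The interval of the difference lay within 2-fold for 20550 probes (63.9%), and for 60.5% of those above the control-spot limit, so larger differences stayed open for the rest. Short of the threshold, with an adjusted p of 1, Spruce_14111 had log2 ratios of 0.59 ± 0.921 (SD, n = 6) at labelled Time 1 and -2.03 ± 1.46 (n = 5) at labelled Time 2. Late trees were well above background for this probe on 1 of 6 arrays of labelled Time 1. Spruce_23362 had -0.26 ± 0.335 and 1.14 ± 0.317, with late trees well above background on 2 of 5 arrays of labelled Time 2. Spruce_02393, not well above background in early trees on any array of labelled Time 1, was there 1.86-fold lower in early trees by floored fold. Late trees were well above background for Spruce_02393 on only 2 of 6 arrays of labelled Time 1, and its log2 ratio was 0.38 ± 0.51 at labelled Time 2. Spruce_14791 was not well above background in either class on any array of labelled Time 1, and in each class on 1 of 5 of labelled Time 2, so no ratio is given.

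Averaged over arrays, the early-late differences and the time change were nearly unrelated across probes. The difference at labelled Time 1 correlated at -0.0355 with the time change in early trees and at 0.0072 in late trees, and the difference at labelled Time 2 at -0.0528 and -0.0541. Single arrays varied more, across the 19901 probes above the control-spot limit in all 4 comparisons. Their correlation with the mean time change ran from -0.343 to 0.24 at labelled Time 1 and from -0.109 to 0.0397 at labelled Time 2.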

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

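The tests of the brightness of the class arrays, and those of the control-spot limit and of shared dye bias for the correlation between times, were chosen only after the result was seen. Outliers were looked for in 58 groups of arrays; 9 were found, where chance alone gives about 2.9.

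The brightness of probes on the class arrays ran against the labelled time change. A scan-day effect would place the array of labelled Time 2 that was scanned together with the arrays of labelled Time 1 on their side, but its slope was -0.443, among the other 4. Normalization is argued against as well, since raw foreground medians with no correction gave r = -0.885. The slope of -0.958 is consistent with an exchange of labels, either of the time labels of the class arrays or of the channels of the time arrays. These data hold nothing that tells the 2 exchanges apart, and no biological explanation was tested.

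The early-late calls at labelled Time 1 lay mostly in dim probes. Dye bias common to all 29 arrays is argued against, since the called probes differed on the time arrays by only 5.24% of their early-late difference. Signal in the Alexa555 channel on spots without target stays a candidate explanation for part of these calls: GFP and Alien spots lay 0.593 below spruce probes of the same brightness (early over late log2 ratio of -0.593, median over 6 arrays, on all 6 by at least 0.2), and the called share fell from 14.3% to 9.13% above the control-spot limit. Leaving out 1 array brought the count under 2297 for 3 arrays (2, 5 and 6) and to 3146, 4851 and 3899 for arrays 1, 3 and 4, so the calls lean more on the first 3, which, as seen only afterwards, also had the highest control-spot signal in the Alexa555 channel (244.5 to 273 against 137 to 222). A probe passes that limit with 1 channel, so the 2061 probes called above it may still hold Alexa555 signal at the control-spot level. The fall of the called share thus does not measure how many calls such signal explains. A real class difference stays open for these 2061 probes too, as does dye bias of the class arrays alone, which all share 1 orientation.

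The early-late differences at both labelled times correlated across probes. The correlation was 0.733 above the control-spot limit (highest other sign pattern 0.726). A probe passes that limit with 1 channel, so probes with Alexa555 signal at the control-spot level stay in. This value therefore decides nothing about signal on spots without target. In the brightest of the 10 groups of probes r was 0.677. Over all probes the correlation was 0.693 without the 2 arrays that resemble each other most across times. The covariance with the channel ratio of the time arrays was 7.68% of that between the class comparisons, which leaves little room for dye bias common to all arrays. Still open are a lasting difference between the classes and chance differences between the genotypes, which both times may share. Alexa555 signal on spots without target and dye bias of the class arrays alone also stay open. The design can set none of these apart.

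The control spots named GFP and Alien, which enter no comparison, carried Alexa555 signal on the class arrays, with a median over the 11 arrays of 210 against 24 in the Alexa647 channel and 12.5 in the Alexa555 channel on the time arrays. Arrays were compared only within their own comparison. Array 5 of labelled Time 2 stood apart with 484 (the next highest of those 5 arrays was 184), and array 9 of the late-tree time comparison with 34 (next 20). Spruce probes were far brighter on array 2 of the early-tree time comparison, with medians of 1040 in the Alexa647 channel and 974 in the Alexa555 channel (next 365 in each), and on array 3 of the late-tree comparison, with 835 in the Alexa647 channel (next 443). Among named probes, Spruce_14926 lay at -7.48 on array 5 of the early trees (next -5.21), and Spruce_19514 at -0.619 on array 4 (next 0.958). Array 9 of the late trees was lowest for Spruce_20463, at 1.74 (next 4.53), and for Spruce_02285, at -0.336 (next 4.96).

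Chance was weighed by turning the signs of whole arrays or by regrouping them. The 4594 calls between early and late trees at labelled Time 1 were matched by 1 of 32 sign patterns, the real one, and the highest other gave 0. This argues against chance between arrays, taken as independent, only as far as 32 patterns allow, since the real pattern alone is the smallest share possible. It says nothing on chance differences between trees or genotypes that arrays may share. Both limits hold for the time calls too. Likewise 1 of 60 drawn patterns, the real one, gave as many calls as the 12877 in early trees (highest other 3166) and as the 13030 in late trees (highest other 6891). At labelled Time 2 the 16 patterns are too few for a share under 0.05; the real count was 0 and the highest other 2. For the difference of the time change, the real count was 0, so 60 of 60 splits give as many by construction and say nothing on chance. The highest other gave 364, and what sets those arrays apart was not tested. For the difference of the early-late difference the real count was also 0, so its 60 of 60 splits say nothing either, and the highest other gave 0.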

How the results depend on the processing

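The alternatives with a control-spot background, the control-spot limit, not-found spots left out, a single scan period, and the 2 most similar class arrays left out were chosen after seeing the data; the others were chosen before the data were examined. Calls of the early-late difference at labelled Time 1 moved from 4594 to 12445 with median centring only, 1192 with the filter against local background, 2061 above the control-spot limit, 2633 with a test on each probe without shared variances, 1240 at an absolute log2 ratio of at least 1 and 1430 at an adjusted p under 0.01. Leaving out each array in turn gave 2117 to 4851, with 2146, 2210 and 2117 without array 2, 5 and 6. At labelled Time 2 the count of 0 became 1532 with median centring, 5686 with all arrays in one fit and 3389 with scan day as a block, and stayed 0 without any 1 array. The time calls moved only with thresholds and few arrays. In early trees they were 4584 at an absolute log2 ratio of at least 1, 8403 at an adjusted p under 0.01, 2064 in the earlier scan period and 10950 to 12597 without 1 array. In late trees they were 4117, 8670, 5913 and 11699 to 12765. The difference of the time change gave 0 to 1 calls without 1 array, and the difference of the early-late difference gave 7 with scan day as a block and 0 without any 1 array. The filters, thresholds and scan periods use fewer probes or arrays by construction; for the other moves the cause was not tested. All other alternatives kept each count within 1.5 times, or at 0.

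Named probes of the time change kept direction and call in all 40 values in early and all 48 in late trees (each array left out in turn, no background correction, and median centring only). At labelled Time 1, 3 of 32 values lost the call (Spruce_16290); at labelled Time 2, 4 of 28 passed the threshold (all with median centring only), and no named probe turned sign. Loess followed by Aquantile left every log2 ratio as it was, and the control-spot background shared 4593 calls with the 4594, since normexp already removes a constant; neither tests anything. No arrays opposed each other within a comparison, so no sign was turned. The deposited table has 1 value per comparison and gives no test; it shared the sign of 4593 of 4594, 12865 of 12877 and 13022 of 13030 calls. Sizes differed more: 4815, 3336, 7201 and 6431 probes had an absolute log2 ratio of at least 1 in that table, in the order early against late at labelled Time 1 and Time 2 and time change in early and late trees, against 1387, 1358, 4697 and 4152 in the fit. Above the control-spot limit of each comparison the counts were 1832, 1534, 5734 and 5029 against 889, 1073, 4601 and 4067. Most of each gap thus lay in probes under that limit, and the cause was not tested. Gene list alternatives were not run. No paired analysis was possible because the labels tie no array of one comparison to an array of another. Signal over background limits what can be said of dim probes: in the Alexa555 channel 26.0% to 75.5% of probes were well above background on the class arrays and 43.7% to 74.6% on the time arrays.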

Other observations

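The test of the time-axis position and that of the agreement of both interaction estimates were chosen only after the result was seen; the test of the spread between class arrays was fixed before.

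Array 3 of labelled Time 1 and array 1 of labelled Time 2 had log2 ratios that correlated at 0.706 across probes, the highest of 30 pairs (next 0.604, median 0.28). Above the control-spot limit the value was 0.747. After print-tip loess and removal of block means it was 0.504, where another pair was highest at 0.605.

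One hypothesis was that early trees were further along the time change than late trees at the same harvest. The slopes of the class arrays on the mean time change lay on both sides of 0. Their mean was -0.0207 ± 0.166 (SD, n = 6, exact permutation p = 0.781) at labelled Time 1, with 3 above and 3 below 0 and a range from -0.281 to 0.166. At labelled Time 2 it was also -0.0207 (SD 0.0427, n = 5, exact permutation p = 0.375, where 0.0625 is the smallest possible). A shared shift of early trees along the time change was thus not seen at either time, but single arrays of labelled Time 1 lay on opposite sides by more than those of labelled Time 2.

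Another hypothesis was that differences between trees set the spread of the class arrays at bright probes. The median SD between arrays was 0.521 for class and 0.465 for time arrays, but the class arrays of labelled Time 1 did not exceed both sets of time arrays: it was 0.454 and 0.543 for the class arrays of labelled Time 1 and Time 2, against 0.422 and 0.476 for the time arrays of early and late trees. In the closest array pair the most variable 1991 of 19901 bright probes correlated at 0.636, over the 0.3 set beforehand, and were not dimmer than the others (median log2 brightness 9.87 and 9.81), as the hypothesis predicts. They were however less correlated than the other bright probes (0.752), as its absence predicts. A high correlation of all bright probes is also what shared genotypes would give, and the genotypes of this pair are not given, so these values decide nothing.

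The difference of the time change between classes can be estimated from the time arrays and, separately, from the class arrays. Both estimates correlated at 0.207 across 19901 bright probes, while 10 of 100 random sign patterns of the class arrays gave as much and the highest 0.286, so no shared difference could be told from chance. With either set of labels exchanged this correlation changes sign.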
